A study of Mus musculus with 12 samples.

How the data were processed

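The series holds 12 mouse cDNA arrays with 2 colour channels, in 6 groups of 2 arrays. Per the labels, the 8 strain arrays carry RNA of the experimental mice in Cy5 and RNA of B6 mice in Cy3, and no array with the dyes exchanged is named. The dyes of the 4 marrow transfer arrays are not given in the sources used here. Their second channel is B6 spleen T cells per the labels, so their direction was taken as that of the other arrays, which stays an assumption. The shared features were also counted with the NODtoB6 arrays turned, a count added after the values were seen. The replicate numbers are not stated to be separate animals, and no sort or gate of the T cells and no age or sex of the mice is given in the sources used here.

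The deposited values are log2 ratios of the experimental channel to the B6 channel, with no normalisation visible. Back-transformed, the values of the 8 strain arrays are whole multiples of 0.001 for 99.8% to 100% of probes (tolerance 0.01 of a step). Those of the marrow transfer arrays carry 3 decimals on the log2 scale, so only 7.3% to 13.9% pass that tolerance. Their values below -2, where this rounding is finer than the step, lie within 0.1 of a step for 100% of probes, so the ratios behind both sets have the same step. The array medians differ by 0.86 on the log2 scale and drift along the probe order by 0.34 to 0.73 between sixteenths of the probes. The tools used upstream are not given in the sources used here. In the strain arrays 146 cells hold the log2 of a ratio of 100000, which was treated as no value. That choice was made after the values were seen. Spot intensities are not analysed here, so signal over background is unknown, no intensity-dependent correction could be made, and a large ratio can come from a dim spot.

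The table lists 20736 probes, of which 13033 carry exactly 1 gene symbol, 312 carry several and 7391 carry none. Symbols were updated through the gene identifier to a RefSeq table of the mouse genome (12850 of 13033 found), giving 8708 genes. Probes of a gene with a value on an array were averaged, 3070 genes have more than 1 probe, and probes without a single symbol were kept as unnamed features, giving 16411 features. Probes of related genes, such as globins, major histocompatibility complex (MHC) genes and interferon-induced genes, can bind each other's RNA. No gene coordinates are given, since no sequence of the probes was mapped.

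Each array was centred on its median over the features used. The groups were fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as group means over the 12 arrays, with 6 residual degrees of freedom and a prior of about 1.4, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. A feature was tested where every array of the groups compared had a value. The 6 groups were compared with B6 as the mean ratio against 0, which leaves out the spread of the B6 control and does not cancel dye bias of single genes. Differences between groups cancel that bias where both sides have the same orientation, and cancel the B6 channel only if both sides used the same B6 RNA, which is not given in the sources used here. NOD-derived T cells (3 groups) were compared with B6-derived T cells (2 groups) on the 10 spleen T cell arrays in a 2-class fit. The group was a random block (duplicateCorrelation, statmod 1.5.0, correlation 0.75). These classes take the T cells of marrow recipients as coming from the donor marrow, which was not measured here. Errors are standard errors of the fit unless stated. Those of the second-list medians and of the excess over pairs of probes come from 1000 bootstrap samples of genes. They take genes as independent and leave out the spread between arrays. The p-values measure the spread between these arrays only, and with 2 arrays per group the number of arrays limits the precision.

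The comparisons, tests, 18 gene lists and the rule for named genes were fixed before the data were examined. The lists are T cell identity and TCR signalling, B cell markers, myeloid markers, erythroid markers, NK and cytotoxic markers, MHC region genes (Idd1), Idd5 region genes, interferon response, T cell activation and regulatory T cells, immediate-early and stress genes, proliferation, apoptosis regulators, Idd candidate genes outside those intervals, chemokines with their receptors, ribosomal proteins, nuclear oxidative phosphorylation genes, kidney segment markers and sex-linked genes. A list's shift was tested with limma's camera in its form for a ranked statistic (cameraPR on moderated t scores, preset correlation 0.01), in place of camera itself because of missing values, with adjustment over all 216 tests. A list is said to pass by this test. An estimated correlation and fry were run beside it, and fry passed for 128 of the tests.

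Named genes were, in each comparison, the 10 with the largest positive and the 10 with the largest negative value past the threshold whose arrays all had the sign of the mean (or did not overlap between the sides), 10 genes named in advance (Ctla4, Icos, Cd28, Slc11a1 and 6 MHC genes), and up to 4 members by moderated t of each list with a shift or a member past the threshold. Where fewer than 3 genes passed in a direction, the 3 with the largest moderated t are given as values. Ctla4, Slc11a1, H2-Ab1, H2-Ea, H2-K1 and H2-D1 had no probe with that symbol alone. The text leaves some of these genes out for length, and genes whose call held under the alternatives were preferred when it was shortened, after the values were seen. Kctd20 is left out because its probes lack values on different arrays.

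Placement on chromosomes 1 and 17 was tested with a Fisher exact test (one-sided). The size of change of the MHC and Idd5 lists was set against 10000 random lists of the same size. Profiles of groups were correlated across features and compared with simulated arrays that share only the B6 RNA. The fit was tested on simulated data with 200 changed features: it recovered 37% to 54% of changes of 1 and 54% to 81% of changes of 2 on the log2 scale in the comparisons of groups (25% and 54% between the classes), with 2.9% to 13% false calls. A simulated list shift of 0.5 was found and no other list was called. The simulation drew features independently and gave a feature the same spread on all arrays, with far fewer changes than were called here. In the real arrays the robust standard deviation of replicate differences ran from 0.11 in kidney to 0.46 in B6toNOD. The simulated shares of recovered and false calls need therefore not hold for these data.

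The alternatives planned before the data were examined were values as deposited, scaling of the arrays to the same spread, other filters on missing values, each probe fitted on its own, robust eBayes, a replicate block, a fit without the kidney arrays, comparison with the mean of the other groups, other forms of the class comparison, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups. Subtraction of a running median along the probe order, removal of a trend on the noise of the feature in the other groups (loess span 0.3), keeping the 146 cells, turning the marrow transfer arrays, all alternatives for the chromosome test, and those for the profile correlation other than features measured on all arrays were added after the data were seen. The noise trend stands in for brightness, and that noise follows the number of arrays lacking a value with a Spearman correlation of only 0.38 across probes. Second lists of granulocyte and monocyte genes and of red cell genes were written for the closing section before they were tested. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.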

Results

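RNA of T cells from the spleen, and in 1 group RNA of kidney cells, was measured on cDNA arrays against RNA of B6 mice. NOD mice develop autoimmune diabetes spontaneously. NOD.H2h4 mice carry another MHC haplotype on the NOD background, and B6.NODIdd1,5 mice are B6 mice with the NOD intervals Idd1, which holds the MHC on chromosome 17, and Idd5 on chromosome 1. The groups, of 2 arrays each, were spleen T cells of NOD, NOD.H2h4 and B6.NODIdd1,5 mice, kidney cells of B6.NODIdd1,5 mice, spleen T cells of B6 mice given NOD marrow (NODtoB6) and of NOD mice given B6 marrow (B6toNOD). Each array gave values for 18837 to 20558 of 20736 probes. Between the arrays of a group the Spearman correlation was 0.62 to 0.87 and Pearson's r 0.51 to 0.76. Both were taken across features, which are not independent replicates. Values below are log2 ratios to B6 after centring each array on its median, with the standard error and n = 2 arrays per group, and p-values are those of limma. Centring moved the median of all features by 0.16 in NOD, 0.81 in NOD.H2h4, 0.18 in B6.NODIdd1,5 T cells, 0.45 in kidney, 0.24 in NODtoB6 and 0.8 in B6toNOD, so every higher or lower is relative to the typical feature of the array.

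**Figure D1:**
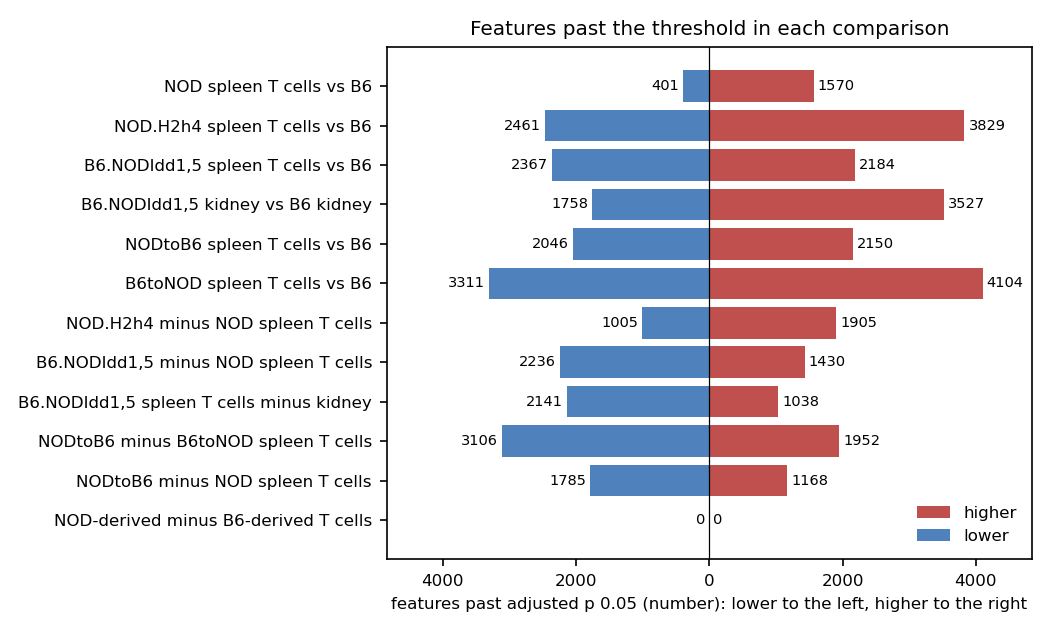
Number of features past an adjusted p of 0.05 in each comparison, lower to the left and higher to the right (bars start at 0, arrays centred). The count was highest in B6toNOD against B6 (4104 higher and 3311 lower) and 0 between NOD-derived and B6-derived T cells. As deposited the split turns in some comparisons (382 higher and 9743 lower in NOD.H2h4, 4038 and 977 in NODtoB6 minus B6toNOD). The fit gives all groups the same spread per feature. Replicate differences were widest in B6toNOD (robust standard deviation 0.46) and narrowest in kidney (0.11), so the counts do not rank the groups by size of change.

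The comparison of NOD with B6 asks which transcripts differ in T cells of the diabetes-prone strain. In NOD spleen T cells, Cd200, which encodes an inhibitory surface glycoprotein, was higher by 3.65 ± 0.067 (adjusted p = 5.1e-07), the nuclear receptor Nr2f2 by 3.52 ± 0.081 and the adult beta globin Hbb-b1 by 3.31 ± 0.13. Hbb-bh1, an embryonic beta globin, was higher by 2.82 ± 0.076, Alas2, the erythroid enzyme that starts haem synthesis, by 1.93 ± 0.16, and the phosphatase gene Ptpn13 by 2.67 ± 0.069. Probes of Ptpn13 (correlation 0.988), Nr2f2 (0.928) and Cd200 (0.916) follow the globin mean over the arrays. Erythroid markers as a list did not pass (median 0.15, adjusted p = 0.11, 0.17 with an estimated correlation; 3 higher, 1 lower, 8 not past). Atic, a purine synthesis enzyme, fell by 3.65 ± 0.52, Wnt2, a secreted signalling protein, by 3.03 ± 0.38, and the heat shock protein gene Hsph1 by 2.40 ± 0.15. Cd28, the costimulatory receptor of T cells, was at 0.59 ± 0.099 (adjusted p = 0.01, which became 0.23 as deposited and 0.092 without NOD replicate 1), and a probe of Cd28 is among those that follow the globin mean over the arrays (correlation 0.925), as is 1 of H2-DMa (0.93). The MHC class II genes H2-Aa (-0.38 ± 0.24, adjusted p = 0.43) and H2-Eb1 (0.37 ± 0.16, adjusted p = 0.21) and Icos, another costimulatory receptor (-0.32 ± 0.62, adjusted p = 0.89), did not pass.

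Myeloid markers shifted up in NOD T cells (median 0.30, adjusted p = 0.017, 0.018 with an estimated correlation): of 14 measured, 5 rose, 0 fell and 9 did not pass, with 5 higher when adjusted over the list alone. S100a9, an abundant calcium-binding protein of neutrophils, rose by 2.16 ± 0.12 and the neutrophil granule gene Ltf by 0.54 ± 0.067. Set against the mean of the other groups, S100a9 was at 0.11, Ltf at -0.29 and the list median at -0.2, and as deposited Ltf no longer passed (0.39, adjusted p = 0.2). The list's call ended without NOD replicate 1 (median 0.24, adjusted p = 0.13) and with features measured on all 12 arrays (0.39, adjusted p = 0.095). Ribosomal protein genes shifted down (median -0.12, adjusted p = 2e-04, but adjusted p = 0.67 with an estimated correlation), with 2 higher, 10 lower and 58 not past, and 3 higher and 12 lower when adjusted over the list alone. Rpl37a fell by 0.85 ± 0.083. Immediate-early and stress genes shifted down (median -0.15, adjusted p = 0.0089, 0.016 with an estimated correlation). Of its members 2 rose, 6 fell and 16 did not pass. There were 3 higher and 9 lower when adjusted over the list alone. Among them the transcription factor Fos fell by 0.90 ± 0.074 and the chaperone Hspa8 by 0.80 ± 0.063. That call ended after subtraction of the running median along the probe order (-0.03, adjusted p = 0.067). Ly6e, an interferon-induced surface protein, fell by 1.87 ± 0.11, while the interferon list as a whole did not pass (median -0.01, adjusted p = 0.5).

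In NOD T cells 1570 features were higher and 401 lower of 15931 tested, with 484 and 202 among named genes. Of all features past the threshold 79.7% were higher. As deposited 106 were higher and 91 lower (53.8% higher), and scaled to the same spread 3166 and 1820 (63.5%), with Cd200 at 6.42, Nr2f2 at 6.2, Hbb-b1 at 5.84, S100a9 at 3.81 and Alas2 at 3.45. Against the mean of the other groups Nr2f2 was at 2.28, Alas2 at 0.97, Fos at -1.41 and Cd28 at 1.06. The total was 836 without NOD replicate 1, 194 without NOD replicate 2 and 1261 without either kidney array.

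NOD.H2h4 T cells differ from NOD T cells in the MHC and linked genes, on the same background. Against B6, S100a9 was higher by 2.33 ± 0.12 and Lcn2, an iron-binding protein of neutrophil granules, by 2.05 ± 0.25 (0.3 and 0.35 against the mean of the other groups, where neither passed). Btk, a kinase of B cell receptor signalling, was higher by 2.11 ± 0.14, Cd200 by 2.03 ± 0.066, Nr2f2 by 1.86 ± 0.081 and Hbb-b1 by 1.85 ± 0.13. Against the mean of the other groups Cd200 was at 0.51, Nr2f2 at 0.3 and Hbb-b1 at 0.52. Ints8, a subunit of the Integrator complex, fell by 5.15 ± 0.68. The transcription factor Jund fell by 4.66 ± 0.40 and Slco1b2, a transporter best known from liver, fell by 4.03 ± 0.50. The hormone gene Retn fell by 3.94 ± 0.65, or 2.46 without NOD.H2h4 replicate 2. H2-Aa fell by 1.68 ± 0.24 (adjusted p = 0.0019), and Cd28 was at -0.58 ± 0.099 (adjusted p = 0.0027, 0.066 with scaled arrays). H2-Eb1 (-0.43 ± 0.16, adjusted p = 0.067) and Icos (-0.83 ± 0.62) did not pass.

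Interferon response genes shifted down in NOD.H2h4 T cells (median -0.45, adjusted p = 0.024, but adjusted p = 0.13 with an estimated correlation). Of its members 2 rose, 8 fell and 7 did not pass. There were 2 higher and 9 lower when adjusted over the list alone. Ly6e fell by 2.07 ± 0.11, the GTPase Gbp2 by 1.83 ± 0.14 and the proteasome activator Psme1 by 0.89 ± 0.095, and the list call ended without NOD.H2h4 replicate 1 (adjusted p = 0.052). Proliferation genes shifted down (median -0.37, adjusted p = 0.028, 0.016 with an estimated correlation), with 2 higher, 9 lower and 24 not past, and the same counts of 2 and 9 when adjusted over the list alone. The replication genes Mcm3 and Pcna fell by 1.71 ± 0.19 and 0.95 ± 0.13, and Birc5, which acts in cell division, by 1.08 ± 0.18. The proliferation call ended as deposited (-1.17, adjusted p = 0.052) and without NOD.H2h4 replicate 2 (-0.41, adjusted p = 0.051). MHC region genes shifted down (median -0.23, adjusted p = 0.047, but adjusted p = 0.38 with an estimated correlation). Of its members 2 rose, 11 fell and 17 did not pass. There were 2 higher and 11 lower when adjusted over the list alone. Agpat1, an enzyme of phospholipid synthesis encoded in the MHC, was higher by 1.22 ± 0.087, while the chromatin reader Brd2 fell by 1.15 ± 0.088 and the chloride channel gene Clic1 by 0.70 ± 0.072. The MHC call ended without either NOD array, NOD.H2h4 replicate 1, either kidney array or either NODtoB6 array (adjusted p 0.055 to 0.12), with other filters on missing values (0.061 and 0.077) and after the running median (0.12). B cell markers had a median of -1.08 with 1 higher, 3 lower and 5 not past (adjusted p = 0.22), among them Cd24a, a surface protein of B cells and other cells, which fell by 0.86 ± 0.097.

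In NOD.H2h4 T cells 1332 named genes were higher and 1595 lower. Of all 15840 features tested 3829 were higher and 2461 lower (60.9% higher), so the surplus of higher features came from unnamed probes. As deposited, where the typical feature lies 0.81 lower, 382 were higher and 9743 lower (3.77% higher), 820 features were called in the opposite direction, and Cd200 was at 1.23, Btk at 1.31 and Agpat1 at 0.42. Without NOD.H2h4 replicate 1 or 2 the total was 3853 or 3873.

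The difference between NOD.H2h4 and NOD T cells cancels the B6 channel if both used the same B6 RNA, which is not given in the sources used here, and addresses the MHC haplotype on the NOD background. H2-Aa was lower by -1.3 ± 0.33 (adjusted p = 0.042) and H2-Eb1 by -0.81 ± 0.23 (adjusted p = 0.047) in NOD.H2h4. Neither call held when any array of these groups, either kidney array or either NODtoB6 array was left out (adjusted p up to 0.19), and H2-Eb1 also missed the threshold without either B6.NODIdd1,5 T cell array (0.061). With scaled arrays H2-Aa was at -0.77 (adjusted p = 0.27). Probes for these polymorphic genes can bind the alleles of the haplotypes unequally. B cell markers had a median of -0.90 in the same difference and did not pass (camera, adjusted p = 0.14, 0 higher, 1 lower, 6 not past). No sort or gate of the T cells is given, so the haplotype is not separated from the cells in the preparations. Cd28 was lower in NOD.H2h4 (-1.18 ± 0.14, adjusted p = 0.0028), as were Clic1 (-0.95 ± 0.10), Brd2 (-0.94 ± 0.12), Gbp2 (-2.10 ± 0.19) and Hbb-b1 (-1.46 ± 0.18, and -4.32 with scaled arrays). Wnt2 was higher by 3.90 ± 0.54 and Hsph1 by 2.72 ± 0.21, Josd1, a deubiquitinase gene, was lower (-3.43 ± 0.54), and Icos did not pass (-0.51 ± 0.87). MHC region genes as a list were lower (median -0.27, adjusted p = 0.035, but adjusted p = 0.34 with an estimated correlation). Of its members 2 were higher, 6 lower and 22 not past. There were 2 higher and 6 lower when adjusted over the list alone. Agpat1 was higher by 1.03 ± 0.12 (0.38, adjusted p = 0.13, as deposited). The list call ended with scaled arrays (-0.32, adjusted p = 0.14), without either NOD array (0.052 and 0.057), without NOD.H2h4 replicate 1 (0.12), with other filters (0.055 and 0.073) and after the running median (0.078).

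Between NOD.H2h4 and NOD 1905 features were higher and 1005 lower of 15570 tested (65.5% higher), with 613 and 617 among named genes. As deposited, where the typical feature lies 0.66 lower, 68 features were higher and 4347 lower (1.54% higher). With scaled arrays 920 features were higher and 1131 lower (44.9%), and Wnt2 was at 6.24 and Hbb-b1 at -4.32. The total was 1627 and 1283 without NOD replicate 1 and 2, and 1038 and 1053 without NOD.H2h4 replicate 1 and 2.

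B6.NODIdd1,5 T cells show what the NOD intervals go with on a B6 background. Against B6, Tcea2, a transcription elongation factor gene, was higher by 6.51 ± 0.51, Msantd1 by 5.86 ± 0.14 and Nt5e, which encodes CD73, an ectoenzyme that makes adenosine, by 4.33 ± 0.39. Entpd1, which encodes CD39, the enzyme that precedes CD73 in the breakdown of extracellular ATP, fell by 3.88 ± 0.43, and Hells, a chromatin remodeller of dividing cells, by 4.15 ± 0.25. Nfkbia, the inhibitor of NF-kappaB, fell by 2.17 ± 0.075 (adjusted p = 4.7e-06), Cd28 by 1.39 ± 0.098 (adjusted p = 8e-05), and S100a9 and Hbb-b1 by 1.25 ± 0.12 and 1.20 ± 0.12 (-3.99 and -3.14 against the mean of the other groups). Of T cell identity genes 0 rose, 5 fell and 5 did not pass (median -0.37, adjusted p = 0.074), with 0 and 5 when adjusted over the list alone. The kinase Fyn fell by 0.85 ± 0.15, a call that ended without B6.NODIdd1,5 T cell replicate 1 (-0.66, adjusted p = 0.063). H2-Aa (0.48 ± 0.24), H2-Eb1 (-0.21 ± 0.16) and Icos (0.26 ± 0.62) did not pass.

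Ribosomal protein genes shifted down in B6.NODIdd1,5 T cells (median -0.22, adjusted p = 2e-04, but adjusted p = 0.67 with an estimated correlation). Of its members 4 rose, 33 fell and 32 did not pass. There were 5 higher and 38 lower when adjusted over the list alone. Rpl4, Rpl5 and Rpl7a fell by 0.89 ± 0.057, 1.08 ± 0.072 and 0.99 ± 0.060. Nuclear genes of oxidative phosphorylation shifted down (median -0.16, adjusted p = 0.0089, but adjusted p = 0.12 with an estimated correlation). Of its members 2 rose, 16 fell and 38 did not pass. There were 2 higher and 16 lower when adjusted over the list alone. Ndufv1 of complex I was at -1.57 ± 0.13, Sdhd of complex II at -1.3 ± 0.088 and Uqcrc2 of complex III at -1.28 ± 0.072. The list call ended after the running median (-0.03, adjusted p = 0.095). Immediate-early and stress genes shifted down (median -0.41, adjusted p = 0.039, but adjusted p = 0.062 with an estimated correlation). Of its members 3 rose, 9 fell and 10 did not pass. There were 3 higher and 10 lower when adjusted over the list alone. Hspa8 fell by 1.25 ± 0.060 and the phosphatase gene Dusp1 by 1.06 ± 0.067. That call ended as deposited (0.052), without a filter on missing values (0.059), against the mean of the other groups (0.2), without either NOD.H2h4 array (0.076 and 0.068) and without B6.NODIdd1,5 T cell replicate 2 (median -0.20, adjusted p = 0.18).

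For the gene lists of the transferred intervals camera did not pass in B6.NODIdd1,5 T cells. Camera looks for a shift in a common direction and cannot find changes that go both ways. Fry, which does not set a list against other genes, passed for both lists. The test of placement did not pass either, but it takes whole chromosomes and so cannot tell about the intervals alone. Of MHC region genes 2 rose, 9 fell and 19 did not pass (median 0.02, mean -0.01, adjusted p = 0.81), with 3 and 9 when adjusted over the list alone. H2-DMa, a chaperone of peptide loading, fell by 1.08 ± 0.13, Skiv2l, an RNA helicase, by 1.86 ± 0.25 and Clic1 by 0.71 ± 0.070. Probes of H2-DMa and Cd28 follow the globin mean over the arrays (correlations 0.93 and 0.925). Of Idd5 region genes 5 rose, 7 fell and 30 did not pass, with the same counts when adjusted over the list alone (median -0.07, adjusted p = 0.72), among them Arpc2, an actin nucleator subunit (-0.92 ± 0.091), and the splicing kinase Clk1 (-0.97 ± 0.097). On chromosome 17, 31.1% of named genes passed against 29.5% elsewhere (one-sided Fisher exact p = 0.26), and on chromosome 1, 30.2% against 29.5% (p = 0.4). The mean absolute moderated t lay at percentile 82.5 of random lists for the MHC list and 81.6 for the Idd5 list. In total 2184 features were higher and 2367 lower of 14705 tested (48% higher), with 887 and 1468 among named genes. As deposited 1039 features were higher and 2839 lower (26.8% higher).

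In kidney cells of B6.NODIdd1,5 mice, compared with B6 kidney, Timm8a1, a mitochondrial import protein gene, was higher by 3.42 ± 0.22. Smpd2, a sphingomyelinase gene, fell by 5.99 ± 0.34. Sap30, a histone deacetylase complex subunit, fell by 5.06 ± 0.69 and the transcription factor Tcfl5 fell by 5.02 ± 0.21. T cell identity genes shifted down (median -0.50, adjusted p = 0.024, 0.028 with an estimated correlation). Of its members 1 rose, 3 fell and 8 did not pass. There were 1 higher and 6 lower when adjusted over the list alone. Cd28 fell by 1.17 ± 0.099, Fyn by 1.01 ± 0.15 and the homing receptor Ccr7 by 0.66 ± 0.090. That list call ended as deposited (-0.96, adjusted p = 0.057), with features measured on all 12 arrays (0.12), against the mean of the other groups (0.11), after the running median (0.056) and with the noise trend removed (0.074). Ribosomal protein genes shifted up after centring (median 0.36, adjusted p = 4.1e-09, but adjusted p = 0.46 with an estimated correlation) and lay below 0 as deposited (-0.1). Of its members 46 rose, 1 fell and 22 did not pass. There were 52 higher and 1 lower when adjusted over the list alone. Rpl12 was higher by 0.84 ± 0.062 and Rps3a1 by 0.80 ± 0.066 (0.34, adjusted p = 0.059, as deposited), and with the noise trend removed the list median was 0.01 (adjusted p = 0.99). Oxidative phosphorylation genes also shifted up after centring (median 0.29, adjusted p = 0.017, but adjusted p = 0.17 with an estimated correlation) and lay at -0.17 as deposited. Of its members 21 rose, 1 fell and 36 did not pass. There were 22 higher and 1 lower when adjusted over the list alone. Atp5b of ATP synthase was at 0.68 ± 0.071 and Uqcrb of complex III at 0.69 ± 0.077, and as deposited neither passed (0.22 and 0.24). This call ended as deposited (0.34), without kidney replicate 1 (0.12), with features on all 12 arrays (0.068), against the mean of the other groups (0.54) and with the noise trend removed (0.57).

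Of kidney segment markers in kidney 4 rose, 1 fell and 10 did not pass (median 0.18, below 0 once the 0.45 shift of all features is put back, adjusted p = 0.5), with 4 and 1 when adjusted over the list alone. Umod, the main urinary protein of the thick ascending limb, was higher by 1.01 ± 0.11 and Lrp2, the endocytic receptor megalin of the proximal tubule, by 0.88 ± 0.12 (0.42, adjusted p = 0.091, as deposited). In the Idd5 list Xrcc5, a DNA repair protein gene, was higher by 1.23 ± 0.14 and Tuba4a, a tubulin gene, fell by 2.49 ± 0.33, while H2-Aa (-0.36 ± 0.24), H2-Eb1 (0.09 ± 0.16, with its probes of opposite sign) and Icos (0.03 ± 0.62) did not pass. In kidney 3527 features were higher and 1758 lower of 15600 tested (66.7% higher), with 1210 and 1031 among named genes. As deposited 441 features were higher and 4707 lower (8.57% higher), and Umod was at 0.55, Xrcc5 at 0.77 and Rpl12 at 0.38. Without kidney replicate 1 or 2 the total was 2546 or 2666.

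The ratios of B6.NODIdd1,5 to B6 were then compared between the tissues. Relative to kidney, the ratio in B6.NODIdd1,5 T cells was higher for Sap30 (7.19 ± 0.97), Msantd1 (7.06 ± 0.19), Tcea2 (6.85 ± 0.72) and Nt5e (5.07 ± 0.55), and lower for Hells (-3.09 ± 0.35). Ribosomal protein genes were lower in T cells (median -0.48, adjusted p = 3.3e-13, but adjusted p = 0.3 with an estimated correlation). Of its members 0 were higher, 48 lower and 21 not past. There were 2 higher and 52 lower when adjusted over the list alone. Examples are Rpl12 (-1.47 ± 0.084) and Rps3a1 (-1.57 ± 0.090). Oxidative phosphorylation genes were lower too (median -0.40, adjusted p = 7.5e-05, 0.016 with an estimated correlation). Of its members 1 were higher, 22 lower and 33 not past. There were 1 higher and 28 lower when adjusted over the list alone. Examples are Uqcrb (-1.68 ± 0.11), Atp5a1 (-1.38 ± 0.12) and Sdhd (-1.43 ± 0.12). Cd28 (-0.21 ± 0.14) and Icos (0.23 ± 0.87) did not differ past the threshold between tissues. Of 14486 features tested in both tissues, 1896 passed in the same direction (1106 higher against 508.1 expected if the calls were independent, 790 lower against 255). In opposite directions passed 505 (123 higher in T cells against 234 expected, 382 lower against 553.5). Kidney also shared more higher calls than expected with NOD (912 against 353.3) and NOD.H2h4 (2102 against 852.1). With the assumed direction it shared 2001 higher calls with B6toNOD (999.2 expected) and 512 lower ones with NODtoB6 (210.6 expected). Sharing above expectation is thus not particular to the congenic strain. In total 1038 features were higher in T cells and 2141 lower (32.7% higher), against 1133 and 432 (72.4%) as deposited, where the typical difference is 0.16, and the total was 1631 and 1635 without kidney replicate 1 and 2.

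Between B6.NODIdd1,5 and NOD T cells, which share the Idd1 and Idd5 intervals and differ elsewhere, Tcea2 (6.64 ± 0.72) and Nt5e (5.17 ± 0.55) were higher in the congenic T cells. Hbb-b1 (-4.52 ± 0.18), Cd200 (-4.35 ± 0.091), Nr2f2 (-4.25 ± 0.11) and Entpd1 (-3.97 ± 0.61) were lower, as were S100a9 (-3.41 ± 0.17), Lcn2 (-2.31 ± 0.35) and Alas2 (-2.79 ± 0.22). With scaled arrays Hbb-b1 was at -7.13, Cd200 at -7.17, Nr2f2 at -6.99, S100a9 at -5.14 and Alas2 at -4.38. Cd28 was lower by -1.98 ± 0.14 (adjusted p = 0.00011), while Icos (0.59 ± 0.87), H2-Aa (0.86 ± 0.33) and H2-Eb1 (-0.58 ± 0.23) did not pass. Oxidative phosphorylation genes were lower (median -0.24, adjusted p = 0.0089, but adjusted p = 0.12 with an estimated correlation). Of its members 1 were higher, 18 lower and 37 not past. There were 1 higher and 19 lower when adjusted over the list alone. Examples are Uqcrc2 (-1.54 ± 0.10), Ndufv3 of complex I (-1.57 ± 0.14) and Sdhd (-1.34 ± 0.12). The list call ended after the running median (-0.07, adjusted p = 0.12). In total 1430 features were higher and 2236 lower of 14451 tested, 725 and 1374 as deposited, 5611 in all with scaled arrays, and 1734 without NOD replicate 2.

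T cells of B6 mice given NOD marrow (NODtoB6) were compared with B6 T cells. The direction of the arrays of both marrow transfer groups is not given in the sources used here and was taken as that of the others, and their values against B6 change sign if it is the reverse. Myeloid markers shifted up (median 0.84, adjusted p = 2e-04, adjusted p = 0.00041 with an estimated correlation). Of its members 8 rose, 0 fell and 6 did not pass. There were 9 higher and 0 lower when adjusted over the list alone. S100a9 rose by 3.05 ± 0.12, Lcn2 by 2.95 ± 0.25, Lyz2, the lysozyme of macrophages and neutrophils, by 2.57 ± 0.089 and the protease inhibitor Cst3 by 1.83 ± 0.083. Hbb-bh1 rose by 3.10 ± 0.075, Hbb-b1 by 2.84 ± 0.13, Alas2 by 2.82 ± 0.16 and Fech, which completes haem synthesis, by 1.85 ± 0.27, although the erythroid list did not pass (median 0.46, adjusted p = 0.16, with 5 higher, 2 lower and 5 not past). Against the mean of the other groups S100a9 was at 1.16, Lcn2 at 1.43 and Hbb-b1 at 1.71. Interferon response genes shifted up (median 0.50, adjusted p = 0.0058, but adjusted p = 0.065 with an estimated correlation). Of its members 6 rose, 0 fell and 10 did not pass. There were 7 higher and 0 lower when adjusted over the list alone. Gbp2 rose by 2.01 ± 0.14, the antiviral membrane protein Ifitm3 by 1.92 ± 0.098 and the GTPase Igtp by 1.25 ± 0.16, and the call ended without NODtoB6 replicate 1 (0.42, adjusted p = 0.079). Oxidative phosphorylation genes shifted up (median 0.28, adjusted p = 2e-04, 0.028 with an estimated correlation). Of its members 23 rose, 3 fell and 33 did not pass. There were 25 higher and 3 lower when adjusted over the list alone. Examples are Ndufv1 (1.31 ± 0.13) and Ndufv2 (1.03 ± 0.10), both of complex I.

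In the same NODtoB6 T cells H2-Aa was higher by 1.66 ± 0.24 (adjusted p = 0.0044). Cd28 was at 0.61 ± 0.099 (adjusted p = 0.0047, and 0.13 as deposited), and H2-Eb1 at 0.62 ± 0.16 (adjusted p = 0.027), whose call ended without either NODtoB6 array (0.15 and 0.13), as deposited (0.24) and against the mean of the other groups (0.068). Icos did not pass (0.25 ± 0.62). Jchain, the joining chain of secreted antibodies, rose by 3.02 ± 0.20 and Cd24a by 1.12 ± 0.096, while B cell markers as a list had 3 higher, 3 lower and 3 not past (median -0.96, mean -0.44, with the test pointing up, adjusted p = 0.98). Other large changes were Cdc16, a subunit of the anaphase-promoting complex, higher by 4.64 ± 0.25, and the receptor gene Erbb3, which fell by 5.22 ± 0.71 (3.36 without NODtoB6 replicate 1), and Slco6c1, which fell by 5.19 ± 0.78. Clec1b, a platelet and myeloid receptor, rose by 3.06 ± 0.20, and the granule protease Gzmm fell by 3.71 ± 0.40. In total 2150 features were higher and 2046 lower of 15288 tested (51.2% higher), against 593 and 3000 (16.5%) as deposited, and the total was 2354 without NODtoB6 replicate 2.

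In T cells of NOD mice given B6 marrow (B6toNOD) several neutrophil and monocyte genes were higher than in B6 T cells. S100a9 rose by 6.68 ± 0.12 (adjusted p = 4.8e-07), Lcn2 by 5.72 ± 0.25, Lyz2 by 3.57 ± 0.088 and Ltf by 2.46 ± 0.065. Myeloid markers shifted up (median 1.39, adjusted p = 0.0068, 0.009 with an estimated correlation). Of its members 8 rose, 1 fell and 3 did not pass. There were 8 higher and 1 lower when adjusted over the list alone. Anxa1, a phospholipid-binding protein of myeloid cells, rose by 4.79 ± 0.18, Smarcd2, a chromatin remodelling subunit needed for granulocyte formation, by 4.64 ± 0.15, Ifitm3 by 4.15 ± 0.097, and Alox5ap, which acts in leukotriene synthesis, by 3.62 ± 0.071. Pcsk5, a proprotein convertase gene, fell by 4.83 ± 0.25 and the Notch ligand Jag1 by 3.63 ± 0.073. The transcription factors Gata1, of red cell precursors, and Gata3, of T cells, fell by 1.14 ± 0.10 and 1.17 ± 0.18, while Hbb-b1 rose by 1.74 ± 0.12 (0.39 against the mean of the other groups). H2-Eb1 was at 0.74 ± 0.16 (adjusted p = 0.0064), -0.02 as deposited, and 0.35 and 1.14 without B6toNOD replicate 1 and 2, while Cd28 (0.19 ± 0.098, adjusted p = 0.14) and Icos (1.31 ± 0.62, adjusted p = 0.11) did not pass.

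Proliferation genes shifted up in B6toNOD after centring (median 0.61, adjusted p = 0.013, 0.009 with an estimated correlation) with a median of -0.15 as deposited: 19 rose, 1 fell and 14 did not pass, with 20 and 1 when adjusted over the list alone. The histone variant H2az1 rose by 2.72 ± 0.11, the tubulin regulator Stmn1 by 2.16 ± 0.088 and the mitotic cyclin Ccnb2 by 1.59 ± 0.14. Ribosomal protein genes shifted up after centring (median 0.65, adjusted p = 5.5e-09, but adjusted p = 0.46 with an estimated correlation) and were at -0.11 as deposited, with 53 higher, 6 lower and 11 not past, and the same counts when adjusted over the list alone. Examples are Rps12 (1.38 ± 0.074) and Rpl11 (1.20 ± 0.065). Oxidative phosphorylation genes shifted up after centring (median 0.70, adjusted p = 3.7e-06, 0.007 with an estimated correlation) and were at -0.06 as deposited. Of its members 37 rose, 2 fell and 19 did not pass. There were 38 higher and 2 lower when adjusted over the list alone. Examples are Ndufs3 (2.01 ± 0.070) and Ndufa12 (1.65 ± 0.074). Immediate-early and stress genes shifted up after centring (median 0.44, adjusted p = 0.035, but adjusted p = 0.062 with an estimated correlation) and were at -0.32 as deposited. Of its members 12 rose, 2 fell and 10 did not pass. There were 13 higher and 2 lower when adjusted over the list alone. Examples are Hspa8 (1.99 ± 0.060), Dusp1 (1.25 ± 0.067) and Fos (1.16 ± 0.072). This last call ended as deposited (adjusted p = 0.14), without B6toNOD replicate 1 (0.085), with features on all 12 arrays (0.068), after the running median (0.052) and with the noise trend removed (0.071). In total 4104 features were higher and 3311 lower of 14296 tested (55.3% higher), against 918 and 8601 (9.64%) as deposited with 568 called the opposite way. As deposited Ccnb2 was at 0.83, Rpl11 at 0.44 and Fos at 0.39, and with scaled arrays the total was 4634 and S100a9 was at 4.21.

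**Figure D2:**
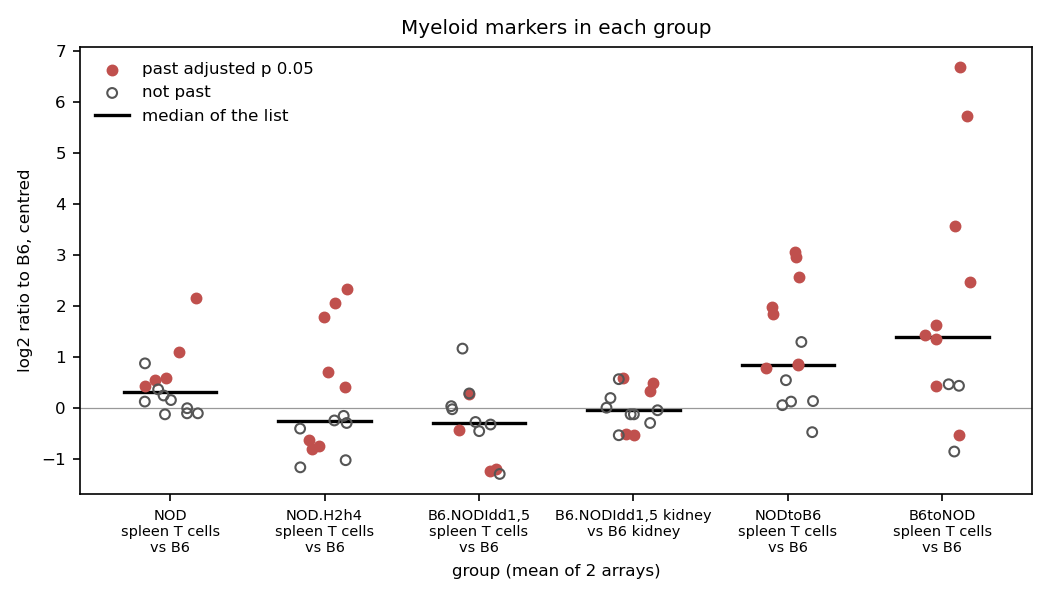
Log2 ratio to B6 (centred, mean of 2 arrays) of each measured myeloid marker in each group, filled where past an adjusted p of 0.05, with the list median as a line. The medians in NODtoB6 (0.84) and B6toNOD (1.39), as deposited 0.61 and 0.62, take the direction of these arrays as that of the others and would be -0.84 and -1.39 if it were turned.

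The direct difference between the marrow transfer groups sets NOD marrow in B6 hosts against B6 marrow in NOD hosts. Each sign in it reverses if the direction of these arrays is not the assumed one. S100a9 (-3.63 ± 0.17, or -0.9 with scaled arrays), Ltf (-1.68 ± 0.090) and Smarcd2 (-4.43 ± 0.21) were lower in NODtoB6, and Plk1, a mitotic kinase, was lower by -4.45 ± 0.65. Ints8 (5.44 ± 0.97), Pcsk5 (4.89 ± 0.35) and Jchain (1.96 ± 0.28) were higher. Erythroid markers were higher in NODtoB6 (median 0.80, adjusted p = 0.047, but adjusted p = 0.084 with an estimated correlation). Of its members 5 were higher, 0 lower and 5 not past. There were 5 higher and 0 lower when adjusted over the list alone. Examples are Hbb-b1 (1.10 ± 0.18) and Gata1 (0.80 ± 0.15, and 0.34 with scaled arrays, adjusted p = 0.15). The erythroid call ended as deposited (1.32, adjusted p = 0.091), with the noise trend removed (0.087), and without either NOD array, NOD.H2h4 replicate 1, either kidney array, NODtoB6 replicate 2 or either B6toNOD array (0.051 to 0.091). Ribosomal protein genes were lower in NODtoB6 (median -0.59, adjusted p = 5.5e-09, but adjusted p = 0.46 with an estimated correlation; -0.06 as deposited). Of its members 4 were higher, 51 lower and 15 not past. There were 4 higher and 53 lower when adjusted over the list alone. Examples are Rps12 (-1.65 ± 0.10). Oxidative phosphorylation genes were lower after centring (median -0.31, adjusted p = 0.026, but adjusted p = 0.21 with an estimated correlation) and at 0.22 as deposited. Of its members 6 were higher, 24 lower and 28 not past. There were 6 higher and 24 lower when adjusted over the list alone. Examples are Ndufs3 (-2.15 ± 0.098). This call ended as deposited (0.076), with scaled arrays (-0.08, adjusted p = 0.59), with the noise trend removed (0.088) and without B6toNOD replicate 2 (0.089). Cd28 was at 0.42 ± 0.14 (adjusted p = 0.047), a call that held without NOD replicate 1 or 2 but ended without any other array (adjusted p 0.053 to 0.16), and H2-Eb1 (-0.12 ± 0.23) and Icos (-1.06 ± 0.87) did not pass. In total 1952 features were higher and 3106 lower of 13676 tested (38.6% higher), against 4038 and 977 (80.5%) as deposited, where the typical difference is 0.51, and 3334 in all with scaled arrays, where Ltf was at -0.7 and Hbb-b1 at 1.97.

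NODtoB6 T cells were also set against NOD T cells, which differ in the host. Both have the NOD genome only if the T cells of the recipients came from the donor marrow, which was not measured here. The signs here rest on the assumed direction of the NODtoB6 arrays. With these turned, the medians of interferon (-0.32, adjusted p = 0.22), myeloid (-1.37, adjusted p = 0.00012) and oxidative phosphorylation genes (-0.33, adjusted p = 0.00053) were lower, and those of immediate-early (0.03) and ribosomal genes (0.07) did not pass. With the assumed direction interferon response genes were higher in the B6 host (median 0.72, adjusted p = 0.00022, 0.016 with an estimated correlation). Of its members 7 were higher, 1 lower and 8 not past. There were 7 higher and 1 lower when adjusted over the list alone. Ly6e was higher by 1.91 ± 0.16, Ifitm3 by 1.83 ± 0.14 and Gbp2 by 1.74 ± 0.19. Immediate-early and stress genes were higher (median 0.32, adjusted p = 0.001, 0.0049 with an estimated correlation). Of its members 10 were higher, 2 lower and 12 not past. There were 12 higher and 2 lower when adjusted over the list alone. Examples are Dusp1 (1.84 ± 0.097), Fos (1.42 ± 0.10) and Hspa8 (0.90 ± 0.087), while the transcription factor Klf4 was lower (-2.61 ± 0.25). Myeloid markers were higher (median 0.80, adjusted p = 0.0037, 0.0069 with an estimated correlation; 0.48 with scaled arrays, adjusted p = 0.18). Of its members 5 were higher, 0 lower and 9 not past. There were 7 higher and 0 lower when adjusted over the list alone. Examples are Lyz2 (1.98 ± 0.13) and Cst3 (1.4 ± 0.12). Oxidative phosphorylation genes (median 0.22, adjusted p = 0.0089, but adjusted p = 0.12 with an estimated correlation; 8 higher, 2 lower, 49 not past, and 8 and 2 when adjusted over the list alone) and ribosomal protein genes (median 0.14, adjusted p = 0.013, but adjusted p = 0.79 with an estimated correlation; 12 higher, 6 lower, 52 not past, and 17 and 7 when adjusted over the list alone) were higher. The former call ended with scaled arrays (0.057) and without NODtoB6 replicate 1 (0.086), and the latter as deposited (0.16) and without NOD replicate 2 (0.11) or NODtoB6 replicate 1 (0.32).

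In this comparison of hosts H2-Aa was higher in NODtoB6 by 2.04 ± 0.33 (adjusted p = 0.0096, and 0.067 without NOD replicate 2 and 0.062 after the running median), and at -1.28 with the NODtoB6 arrays turned. Cdc16 was higher by 5.41 ± 0.36 and Pfkp, a glycolytic phosphofructokinase gene, by 3.85 ± 0.58. Cd28 (0.02 ± 0.14), H2-Eb1 (0.25 ± 0.23) and Icos (0.57 ± 0.87) did not pass, while with the arrays turned Cd28 (-1.21) and H2-Eb1 (-0.99) did. In total 1168 features were higher and 1785 lower of 15029 tested (39.6% higher), against 324 and 1150 (22%) as deposited and 4870 in all with scaled arrays, where Ly6e was at 3.31, and the total was 948 without NOD replicate 2. The arrays analysed here hold no transfer of B6 marrow into B6 mice, so host and transfer are not separated.

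Between NOD-derived and B6-derived T cells limma called 0 of 12560 features with the group as a block, and 747 had an unadjusted p under 0.05, where 628 would be expected by chance. The largest moderated t upward were those of the translation repressor gene Eif4ebp2 (1.94 ± 0.32), Ngb (1.89 ± 0.38) and Ptpn13 (2.27 ± 0.48), and downward those of Chchd2 (-1.98 ± 0.32), Clec4e (-1.50 ± 0.31) and Rb1cc1 (-1.21 ± 0.29), with adjusted p from 0.44 to 0.79. Hbb-b1 (2.40 ± 0.72), Cd28 (0.80 ± 0.49) and Icos (-1.09 ± 1.3) did not pass. Ribosomal protein genes as a list were lower in NOD-derived T cells (median -0.26, adjusted p = 2e-04, but adjusted p = 0.67 with an estimated correlation), with 0 of 69 members past the threshold in either direction, also when adjusted over the list alone. This direction rests on the assumed one of the marrow transfer arrays: with these turned the list was at 0.39 (adjusted p = 7.5e-05), and 4 features passed. With the arrays taken as independent 42 features passed (32 higher, 10 lower), and as a contrast of group means in the fit of 12 arrays 4776 (2399 higher, 2377 lower).

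With the assumed direction of the marrow transfer arrays, the groups with NOD marrow or genome shared 294 features higher in NOD, NOD.H2h4 and NODtoB6 T cells (87 of them named genes), against 53.6 if the calls were independent and 172 given what NOD and NOD.H2h4 share, and 19 lower (8 named) against 6.73 and 15.9, of 14813 tested in all of them. With the NODtoB6 arrays turned the numbers would be 246 higher (65 named) against 52 and 167, and 24 lower (14 named) against 6.93 and 16.4, so a large part of this sharing follows from that of NOD and NOD.H2h4. The named genes of the assumed direction include Cd200, Nr2f2, Hbb-b1, Alas2, S100a9 and Lcn2. Of these Cd200 (1.58), Nr2f2 (1.96), Hbb-b1 (1.74), S100a9 (6.68) and Lcn2 (5.72) were also higher past the threshold in B6toNOD T cells, again with the assumed direction. Sharing of higher features is not particular to NOD-derived groups. With the assumed direction NOD shared 442 with NODtoB6 (213.5 expected) and 890 with B6toNOD (441.8 expected), and it shared 912 with kidney (353.3 expected). Lower features shared were 47 with NODtoB6 (46.58 expected), 49 with B6toNOD (78.37) and 56 with kidney (43.63). Features higher in NOD and lower in the other group numbered 268 in NODtoB6 (208.7 expected), 288 in B6toNOD (360.5) and 150 in kidney (176.9). Those lower in NOD and higher in the other group numbered 84 (47.65), 183 (96.04) and 149 (87.13), each above expectation. Since each T cell group is set against RNA of B6 T cells, part of the sharing between T cell groups may come from the B6 sample. NOD and NOD.H2h4 shared 1258 higher features (382.6 expected) and 138 lower (57.04 expected), and their profiles correlated across features with Pearson's r of 0.5 and Spearman's rho of 0.53 and a covariance of 0.156. Simulated arrays that share only the B6 RNA gave 0.5, 0.44 and 0.0982. The simulated r of 0.5 follows from the equal spread given to the B6 sample and both groups. It therefore cannot tell whether shared B6 RNA accounts for the observed r. The other pairs of groups had Pearson's r between -0.01 and 0.31. Their covariances lay between -0.00436 and 0.209, the highest between NODtoB6 and B6toNOD and above that of NOD and NOD.H2h4.

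No test for more changed genes on chromosome 1 or 17 passed after adjustment (one-sided Fisher exact tests, lowest adjusted p = 0.06). The lowest was NODtoB6 on chromosome 1, where 31.6% of named genes passed against 25.6% elsewhere (unadjusted p = 0.0027), and adjusted p fell to 0.025 without NODtoB6 replicate 2. The mean absolute moderated t of MHC region genes lay at percentile 97.5 of random lists in NODtoB6, 99.2 in the difference of the marrow transfer groups and 96.2 in NOD.H2h4 minus NOD. That of Idd5 region genes lay at 98.4 in NOD.H2h4 and 99.5 in NOD.H2h4 minus NOD. These are the 5 in the top 5% among 24 percentiles, which range from 22.5 to 99.5. Chance would give 1.2 on average, and comparisons that share arrays are not independent.

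By camera some lists passed in none of the 12 comparisons, and the lowest adjusted p of each is given here. B cell markers were lowest in NOD.H2h4 minus NOD (median -0.90, adjusted p = 0.14, 0 higher, 1 lower, 6 not past), and NK and cytotoxic markers in NOD (median -0.30, adjusted p = 0.071, 0 higher, 1 lower, 5 not past). Apoptosis regulators were lowest in B6.NODIdd1,5 T cells (median -0.27, adjusted p = 0.27, 0 higher, 6 lower, 9 not past), where the survival gene Bcl2l1 fell by 1.52 ± 0.21. T cell activation and regulatory T cell genes were lowest in B6.NODIdd1,5 T cells minus kidney (median 0.20, adjusted p = 0.37, 1 higher, 0 lower, 9 not past). Idd candidate genes outside Idd1 and Idd5 were lowest in NOD (median -0.10, adjusted p = 0.59, 1 higher, 1 lower, 15 not past), and chemokines and their receptors in NODtoB6 (median 0.60, adjusted p = 0.59, 4 higher, 1 lower, 7 not past). Idd5 region genes (median 0.11, adjusted p = 0.43, 16 higher, 6 lower, 21 not past) and kidney segment markers (median -0.59, adjusted p = 0.32, 1 higher, 4 lower, 6 not past) were lowest in B6toNOD, where the typical feature lies 0.8 lower as deposited. Sex-linked genes were lowest in B6.NODIdd1,5 T cells (median -0.27, adjusted p = 0.44, 0 higher, 2 lower, 3 not past). Adjusted over the list alone, the higher and lower members were 0 and 2 for B cell, 0 and 1 for NK, 0 and 6 for apoptosis, 1 and 0 for T cell activation, 1 and 1 for Idd candidate, 5 and 2 for chemokine, 16 and 6 for Idd5, 1 and 6 for kidney and 0 and 2 for sex-linked genes.

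**Figure D3:**
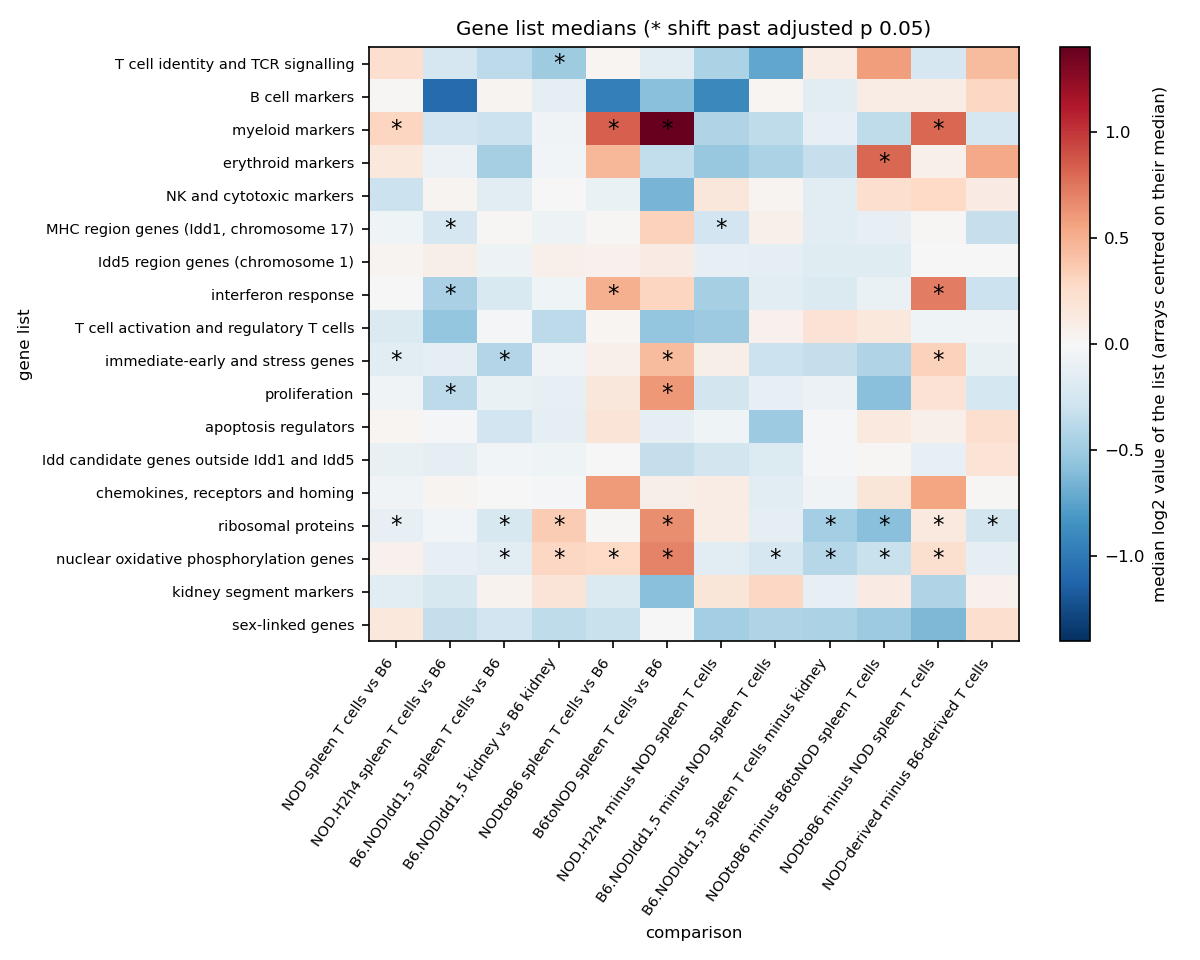
Median log2 value of each gene list in each comparison, arrays centred, with a star where the shift passed an adjusted p of 0.05. As deposited the medians of ribosomal and oxidative phosphorylation genes in kidney and of proliferation, ribosomal, oxidative phosphorylation and immediate-early genes in B6toNOD turn negative, while that of oxidative phosphorylation genes in NODtoB6 minus B6toNOD turns positive.

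**Figure D4:**
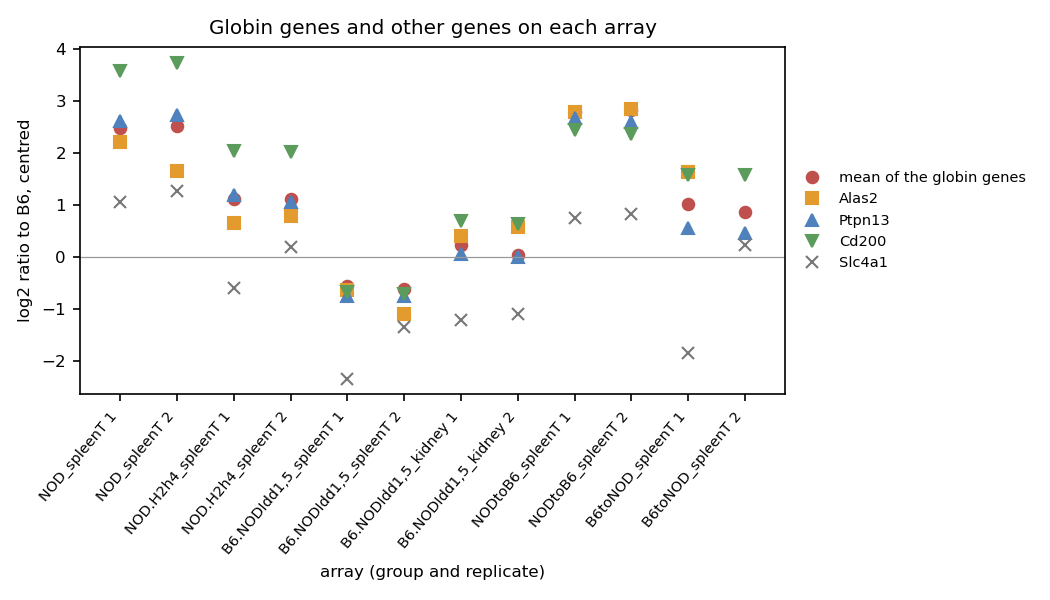
Mean centred log2 ratio of the globin probes on each array, beside Alas2, Ptpn13, Cd200 and Slc4a1, a membrane protein gene of red cells. The mean was 2.47 and 2.52 in NOD, 2.78 and 2.83 in NODtoB6, and -0.56 and -0.62 in B6.NODIdd1,5 T cells, and in kidney (0.23 and 0.04) it turns negative as deposited.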

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

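No test in this part was chosen after its result was seen. The ratio of B6.NODIdd1,5 to B6 differed between tissues by a test of the difference itself (n = 2 arrays in each tissue). Whether the intervals account for these ratios was not tested. Between B6.NODIdd1,5 T cells and kidney cells, each against B6 of the same tissue, 3179 features differed past the threshold in limma, and as deposited 1565. In opposite directions in the tissues were 505 features (123 against 234 expected from independent calls and 382 against 553.5). All 505 passed the test of the difference in limma, which their choice by opposite signs makes nearly certain. Ribosomal protein genes had a median difference of -0.48 and oxidative phosphorylation genes one of -0.4, lower in T cells also as deposited (-0.19 and -0.12). With an estimated correlation the ribosomal shift did not pass (adjusted p = 0.3 in limma) and the other did (0.016). In kidney alone these families lie above 0 after centring and below 0 as deposited. The tissue stays open as a biological explanation and was not tested apart from the arrays of each tissue.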

How the results depend on the processing

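The running median along the probe order, the noise trend, the turned marrow transfer arrays, every alternative for the chromosome tests and the leaving out of arrays for the correlation were chosen only after the data were seen. The cause of the changes below was not tested. As deposited, the counts of changed features became 197 in NOD, 10125 in NOD.H2h4, 4415 in NOD.H2h4 minus NOD, 2099 in B6.NODIdd1,5 minus NOD, 1565 in B6.NODIdd1,5 T cells minus kidney and 1474 in NODtoB6 minus NOD. With scaled arrays they became 4986 in NOD, 4634 in B6toNOD, 5611 in B6.NODIdd1,5 minus NOD, 3334 in NODtoB6 minus B6toNOD and 4870 in NODtoB6 minus NOD. The NOD count was 1261 without the kidney arrays. In kidney it was 9689 in a fit of the groups compared and 3219 against the mean of the other groups. After the running median NODtoB6 minus NOD had 1889. Between the classes 42 features passed with arrays taken as independent and 4776 as a contrast in the fit of 12 arrays.

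With the marrow transfer arrays turned, their values against B6 and their difference from each other only change sign, so only 2 comparisons were run anew. Between the classes 4 features passed and the ribosomal median reversed to 0.39. In NODtoB6 minus NOD the medians of myeloid (-1.37), interferon (-0.32) and oxidative phosphorylation genes (-0.33) reversed, as did Cdc16 (-3.86), Ifitm3 (-2), Gbp2 (-2.28), Dusp1 (-2.61), Klf4 (2.27), Lyz2 (-3.16), Cst3 (-2.26) and H2-Aa (-1.28).

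Leaving out 1 array gave counts of 194 to 2476 in NOD, 3853 to 7563 in NOD.H2h4, 3462 to 5580 in B6.NODIdd1,5 T cells, 2546 to 6442 in kidney, 2354 to 5533 in NODtoB6 and 6903 to 7744 in B6toNOD. For the differences they were 1038 to 3913 (NOD.H2h4 minus NOD), 1734 to 4689 (B6.NODIdd1,5 minus NOD), 1631 to 3940 (T cells minus kidney), 4013 to 5871 (NODtoB6 minus B6toNOD) and 948 to 3989 (NODtoB6 minus NOD), and 0 to 0 between the classes. The lone array of a group is assumed to vary like the other groups.

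List shifts past the threshold numbered 33 of 216, 13 with an estimated correlation, 128 with fry and 28 to 36 without 1 array. The myeloid median in NOD reversed to -0.2 against the mean of the other groups, as did Ltf (-0.29), and H2-Eb1 in B6toNOD reversed to -0.02 as deposited. Of 192 gene values past the threshold 164 stayed past it in the same direction under every alternative run, 21 did not pass under at least 1, and 10 reversed, with 3 values in both of the last numbers. The mere changes of sign named above are not counted. This share is raised by the choice of genes for the text, which preferred calls that held, and is no measure for the other genes. Chromosome tests past the threshold numbered 0, but 2 with no filter on missing values, 2 with the noise trend removed, 2 with robust eBayes, 1 after the running median and 0 to 2 without 1 array. The correlation of NOD and NOD.H2h4 was 0.5, and 0.49 over features on all arrays, 0.44 after the running median, 0.4 with the noise trend removed and 0.47 to 0.48 without 1 array. Signal over background is unknown, which limits all ratios of dim spots.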

Other observations

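The tests of drift along the probe order, of a lower T cell share, of spots with globin sequence and of the class splits were chosen only after the result was seen. Globin probes and genes of other families moved together over the arrays. Of 14883 probes with a value on all arrays 81 correlated above 0.9 with the globin mean and 9 at the opposite sign. They include Ptpn13 (0.988), Atp6v0d1 (0.97), H2-DMa (0.93), Nr2f2 (0.928), Cd28 (0.925) and Cd200 (0.916), and also the red cell genes Mkrn1 (0.95), Fech (0.938), Bpgm (0.924) and Tfrc (0.901), named here after their values were seen.

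Red cell RNA in the T cell preparations is a candidate explanation for this globin pattern. In a second list of red cell genes, of which 19 of 30 on the array are widely expressed and 0 are in another list, the median was 0.22 ± 0.082 in NOD (positive in 22 of 29) and 0.38 ± 0.21 in NODtoB6 (16 of 27). Its shift passed in NOD and missed the threshold in NODtoB6, so this stays open. The errors of second-list medians are taken over genes, not arrays. Among genes known for high expression in red cell precursors, whose abundance was not measured here, Hbb-b1 was at 3.31 in NOD and 2.84 in NODtoB6 and Alas2 at 1.93 and 2.82, while Slc4a1, a main membrane protein gene of red cells, was higher with the globins on the NOD arrays (1.05 and 1.27) and the NODtoB6 arrays (0.75 and 0.83) and not on others (-1.84 and 0.23 in B6toNOD, -0.59 and 0.19 in NOD.H2h4). Removal of red cells is not given in the sources used here. Spots that carry globin sequence in place of the named gene may also take part, which stays open. Of 20 other probes of the same genes 0 followed the globin mean, a difference of -0.544 points (standard error 4.9) from all probes. Other probes of a gene shared the sign of a called probe in only 60.3% of pairs against 51.3% expected. Few would therefore follow with any cause, and the count cannot tell. Strain and marrow origin stay open. Hbb-b1 did not pass between NOD-derived and B6-derived T cells. With the assumed direction it was higher in NODtoB6 than in B6toNOD (1.1), where marrow and host differ together.

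With the assumed direction of their arrays, myeloid markers were higher in both marrow transfer groups, and myeloid cells in the preparations are a candidate source. A second list of granulocyte and monocyte genes (21 on the array, 6 widely expressed, 0 in another list; 3 of the 14 in the first list are widely expressed) had medians of 0.45 ± 0.1 in NODtoB6 and 0.7 ± 0.3 in B6toNOD, positive in 18 and 16 of 21 genes. Genes known for high expression in such cells, whose abundance was not measured here, include S100a9 (3.05 and 6.68), Lyz2 (2.57 and 3.57), Cd177 (1.38 and 2.93) and Cyba (0.65 and 1.75). Against it, the neutrophil receptor gene Csf3r fell in both (-0.22 and -0.28) and Plaur was at -0.22 in both without passing, and any sort or gate is not given in the sources used here. Brightness bias stays open, since only a trend on noise could be removed (the myeloid median kept at least 0.8 of its size) and that noise is a weak stand-in for brightness. A lower T cell share alone stays open, and its test set B cell against myeloid markers without using the T cell identity genes. B cell markers (medians -0.96 and -0.59) lay below myeloid markers (exact permutation p = 0.018 and 0.014), but the permutation takes the genes as independent and B cell members went both ways (3 higher and 3 lower in NODtoB6, 2 and 1 in B6toNOD). With the estimated correlation within lists (0.44 for B cell markers) the difference of means was 1.61 ± 1.4 in NODtoB6 and 2.43 ± 1.1 in B6toNOD. A change within T cells and an effect of the transfer stay open and untested.

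Large shares of features passed against B6. Drift along the probe order as the whole cause is argued against: after its correction each count was at least 0.77 of the first, though in NOD only 1283 of the 1971 features were the same. Brightness bias stays open: with the trend on noise, a weak stand-in for brightness (Spearman correlation with missing values 0.38), removed, each count was at least 0.74 of the first, but only 1091 of 1971 features were the same in NOD and 3099 of 5285 in kidney. Errors of single spots repeated on both arrays stay open: another probe of the same gene had the sign of a called probe in 60.3% of 21567 pairs against 51.3% expected, an excess of 8.98 ± 0.77 points between the bounds of 5 and 20 set in advance. By group the excess ran from 4.62 points in kidney, below the lower bound, to 15.6 in NOD. Dye bias of single genes, which does not cancel in the ratios to B6, stays open and untested, as do strain and tissue.

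Of the 10 splits of the 5 T cell groups into classes of 3 and 2, 6 gave at least as many features at an unadjusted p under 0.05 as the real one, the real one included (747, highest other 1287). The splits are too few for a share under 0.05.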
